A study of Mus musculus with 6 samples.

How the data were processed

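RNA from mPAC L20 cells, a mouse pancreatic duct line, was hybridised as biotin-labelled cRNA to 6 Affymetrix arrays. All cells carried an adenovirus that expresses Neurog3. A second adenovirus, added before it, carried either a scrambled hairpin (shControl, 3 arrays) or a hairpin against Atoh8 (shAtoh8, 3 arrays). Per the labels' protocols, 250000 cells were seeded per well, each virus was used at a multiplicity of infection of 40, the hairpin virus stayed on for 4 h and the Neurog3 virus for 1.5 h, and culture went on for 44 to 46 h. The replicates were independent experiments, per the labels.

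The deposited values are log2 signals per probe set; the values show the log2 scale, and RMA in the affy package made them, per the submitters' processing notes. RMA corrects background, quantile-normalises and summarises the probes of a set, so the arrays had already been put on a common distribution, and a shift of most genes in one direction would have been removed. The versions of RMA and affy are not given in the sources used here. The deposited table held 45101 probe sets. The 64 control probe sets were left out of the tests, and 45037 were tested without a filter on brightness. The number of arrays limits the precision of each value.

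Gene names came from the platform annotation supplied for the probe sets: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were compared through Entrez IDs with a RefSeq gene table (GRCm38.p6), which was used for names alone and changed 0 symbols. A probe set with several symbols or none named no gene. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays.

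The comparison was shAtoh8 against shControl, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 4 residual and 3.30 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 45037 probe sets, with a threshold of 0.05. Errors of fold changes are limma's moderated standard errors. The 26 gene lists held 874 entries, of which 783 matched a measured gene. The lists were tested with camera, a competitive test, at a preset correlation of 0.01 between genes, with adjustment over the 26 lists. The mean of a list on each array was compared by an exact permutation test, for which 3 arrays against 3 cannot give a p below 0.1. It treats the arrays as unpaired, and an exact sign test over 3 pairs cannot go below 0.25.

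Genes were named by a fixed rule: Atoh8 and Neurog3; in each direction the 15 largest changes among genes past the threshold whose groups did not overlap, clone-like names left out; and in each list up to 4 members that passed (8 in the cell cycle lists), or the 2 with the smallest p where none passed. The groups, the test, the lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

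The shared replicate numbers were checked for pairing. Deviations from the group means over all probe sets correlated between arrays of the same number at 0.407, 0.187 and 0.433, and between arrays of different numbers at -0.351 to 0.0292. The numbers were therefore taken to pair the arrays, and the fit with the replicate number as a block is given where it changed a call or a count. Alternatives covered normalization, centring, a brightness filter, the block, the variance model, array weights, each array left out, other thresholds, a minimum fold of 1.5, the choice of probe sets, and for the lists an estimated correlation and the self-contained test fry, read for a shift in one direction.

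The fit was tested on simulated arrays with the real means, 200 of 45037 probe sets changed and 20 runs per setting, for the comparison of shAtoh8 with shControl. Noise was first drawn with each probe set's moderated variance from the fit without the block. With no pair effect, 16.5% of changes of 0.5 (log2), 90.9% of changes of 1 and 99.6% of changes of 2 were recovered. Of the calls 7.65% were false, above the nominal 5%. A pair effect of the same SD was then added on top. That variance already holds spread between replicate numbers, so the simulated spread with pairs exceeds the one fitted to the data. The fit without the block then recovered 0.224%, 56.3% and 97.8% with 0.919% false calls. The fit with the block recovered 2.54%, 87.6% and 99.5% with 8.46% false calls. When variances were drawn from the distribution limma assumes, the false share with neither a pair effect nor the block was 5.50%, and 74.6% of changes of 1 were recovered. With a pair effect under that variance model, 29.9% of changes of 1 were recovered without the block (0.442% false calls) and 38.1% with it (4.65%). A simulated list shifted by 0.3 among the 18193 genes was found in 100% of runs; the simulated genes were independent, so this says nothing of correlated lists.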

Results

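Expression was measured on 6 arrays of mPAC L20 cells, a mouse pancreatic duct line in which an adenovirus expressed Neurog3, the transcription factor that starts endocrine differentiation in the pancreas. In 3 samples a second adenovirus carried a scrambled hairpin (shControl) and in 3 it carried a hairpin against Atoh8, a basic helix-loop-helix transcription factor (shAtoh8). The array medians lay between 5.49 and 5.56 (log2 signal). The replicate 2 array of shAtoh8 had weaker hybridisation spikes (9.28, against 9.67 to 9.89 on the other arrays) and a wider gap between the 3' and 5' actin probe sets (0.354, against 0.107 to 0.202). None of the 64 control probe sets changed in limma (0 at an adjusted p under 0.05, 2 at an unadjusted p under 0.05).

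Atoh8, the target of the hairpin, had a lower mean in shAtoh8, but the difference did not pass the test. Its single probe set read 8.75, 8.29 and 7.52 in shControl replicates 1, 2 and 3, and 7.83, 7.90 and 7.37 in shAtoh8. The means were 8.19 ± 0.62 and 7.70 ± 0.29 (SD, n = 3 each), a log2 fold change of -0.49 ± 0.30 (SE) or 1.40-fold lower, with a limma adjusted p of 0.573. All 3 pairs were lower in shAtoh8, by log2 differences of -0.92, -0.39 and -0.15, and with the replicate block the adjusted p was 0.157. With 1 array left out at a time the fold change ranged from -0.82 to -0.21.

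Neurog3, expressed from the virus in both groups, gave different signs on its probe sets. The log2 fold change was -0.57 ± 0.48 (SE) on the brighter probe set (limma adjusted p = 0.706) and 0.18 ± 0.17 on the other (adjusted p = 0.751). With 1 array left out at a time these ranged from -0.99 (without shControl replicate 3) to -0.16 (without shControl replicate 1) and from 0.02 (without shControl replicate 3) to 0.28 (without shAtoh8 replicate 3). On the brighter set the level differed more between replicate numbers (7.45, 6.64 and 5.79 in shControl) than between groups. All 3 pairs were lower there, by -0.67, -0.58 and -0.46, and the difference passed with the replicate block (adjusted p = 0.0330), while the other probe set did not (0.400). Which part of the transcript each probe set reads, and whether it sees the viral copy, was not analysed here.

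**Figure D1:**
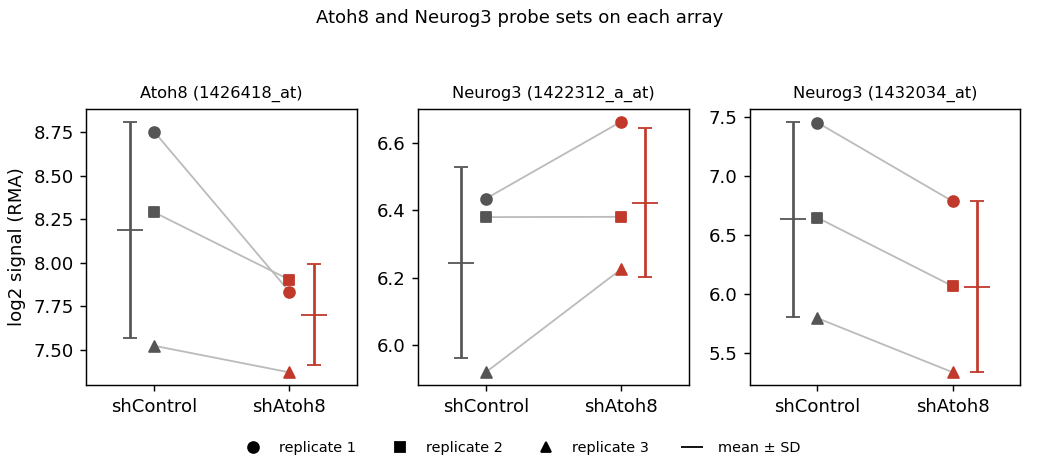
Log2 signal (RMA) of the Atoh8 probe set and both Neurog3 probe sets on each of the 6 arrays, with lines joining arrays of the same replicate number and bars for the mean ± SD (n = 3); the vertical axes differ. Atoh8 was lower in shAtoh8 in each pair, but the shControl arrays spanned 7.52 to 8.75 and the groups overlap.

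Which genes differ when the Atoh8 hairpin replaces the scrambled one is the question of the design. The largest rises were those of Apmap (log2 1.60 ± 0.14 SE, 3.03-fold), Trp53inp1, a p53-induced gene (1.47 ± 0.13), Mctp2 (1.47 ± 0.20), Mfsd1, a lysosomal membrane transporter (1.47 ± 0.11), and Yipf6 (1.46 ± 0.20). Asah1, the lysosomal acid ceramidase, rose by 1.43 ± 0.10, from 9.83 ± 0.11 to 11.27 ± 0.10 (SD, n = 3). Rcan2, Rnase1, Rnf181, Grk5, Tgfbr1, Tbc1d20, Snap23, Cpped1 and Celf5 rose by 1.24 to 1.39. The largest falls were those of Pcgf3, a Polycomb ring finger protein (-1.98 ± 0.12, 3.95-fold lower), the transporter Abcc4 (-1.94 ± 0.18), the lysine methyltransferase Setd7 (-1.93 ± 0.15) and the receptor Lifr (-1.74 ± 0.27). Cttnbp2nl, Zdhhc21, Man2a1, Sinhcaf, Fut11, Tmem9b, Frmd6, Slc10a7, Cenpa, Sertad4 and Anln fell with log2 changes of -1.36 to -1.65. The other probe set of Setd7 had the opposite sign, as had 1 of the other 2 probe sets of Yipf6 and of Cenpa and 1 of the other 3 of Slc10a7. Sizes and ranks depend on the probe sets: as the mean of a gene's probe sets Pcgf3 read -0.97, Setd7 -0.94, Lifr -0.89, Slc10a7 -0.73 and Cenpa -0.47, and Rnf181 0.85, Tbc1d20 0.80, Cpped1 0.71 and Yipf6 0.48. Abcc4, with 1 probe set, then had the most negative value of the named falls (-1.94). The value of Yipf6 rests on the choice of its brightest probe set: without shAtoh8 replicates 1, 2 and 3 another set was brightest, with log2 fold changes of 0.06, 0.10 and 0.02 (adjusted p = 0.894, 0.756 and 0.963), while the set used here stayed at 1.45, 1.47 and 1.46 (0.116, 0.0648 and 0.103).

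In all, 210 of 18193 genes changed (limma adjusted p under 0.05), 94 higher and 116 lower, and 361 of 45037 probe sets (138 and 223). Of these genes 64 changed at least 2-fold, the median absolute log2 change was 0.82, and 145 had several probe sets, which all had the same sign for 109. Of the 18193 genes, 765 had a more negative fold change than Atoh8. With the replicate block 849 genes passed (349 higher, 500 lower), the 210 among them. Each replicate number gave 1 array to each group, so the block leaves every fold change and its sign as they were. Without both arrays of replicate 1, 2 or 3, in fits chosen after the data were seen, the block fit gave 0, 962 and 0 genes. All 3 arrays of one group lay above the other group for 4368 genes (24.0%, where chance gives 10% for arrays that are not paired). The other 3 splits that part all 3 pairs, a comparison chosen after the data were seen, gave 5.15%, 7.11% and 4.58%. Those splits hold both hairpins in each group, so a difference between hairpins would widen their spread and lower these shares. They are therefore not a clean baseline for the 24.0%. The count rested on every array: it was 3 without shControl replicate 1, 0 without shControl replicate 2 (2642 at an unadjusted p under 0.05), 22 without shControl replicate 3, and 1, 115 and 41 without shAtoh8 replicates 1, 2 and 3. In each of these fits the 210 genes had the same sign, and 209 or 210 of them had an unadjusted p under 0.05 (limma). The groups did not overlap for any of the 210, so on the same probe set the sign was fixed in advance. Their median absolute log2 change there was 0.77 to 0.85. The 210 had been chosen in the fit to all 6 arrays, so none of these values is a separate check of the calls. The 42 called genes named in the text by the fixed rule all lost their call without shControl replicate 2. Taking the mean of a gene's probe sets ended the calls of Yipf6, Tgfbr1, Lifr, Cenpa, Ccnd3, Ercc5, Birc3, Dnajc3 and Ern1 (adjusted p from 0.0516 to 0.153). The values were then -0.24 for Ccnd3, 0.32 for Ercc5, -0.35 for Birc3 and -0.39 for Ern1. Leaving out probe sets marked for cross-hybridisation ended the calls of Cttnbp2nl (0.0930), Jag2 (0.0502) and Lyz2 (0.0521), which also missed the threshold with median centring (0.0594) and with the trend and robust variance model (0.0506).

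The series title points to cell cycle genes, so the cell cycle lists are not independent of what the submitters had seen. In this and the other lists, members named for passing over the list alone or with the replicate block, outside the fixed rule, were chosen after their values were seen. Counts with the replicate block are over all probe sets, except where the list alone is named. Genes of G2/M and mitosis were lower as a group: 51 of 52 measured members had a negative fold change, with a median of -1.04 and a camera adjusted p of 2.57e-30. This call was lost when the correlation between genes was estimated from the residuals (0.81, adjusted p = 0.572 with an estimated correlation). Anln, a cytokinesis scaffold (-1.36 ± 0.18 SE), and Cenpa, the centromeric histone (-1.39 ± 0.21), fell past the threshold over all probe sets, and with the replicate block 32 members fell. When adjusted over the list alone, 50 members passed lower, and 50 with the block. Bub3, singled out after the values were seen, was the member with a positive value (0.10, adjusted p = 0.681). The list mean was 8.55, 8.34 and 8.32 in shControl and 7.65, 7.77 and 6.89 in shAtoh8, without overlap (exact permutation p = 0.1, the smallest possible).

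Genes of the G1/S transition and DNA replication were lower too, with 45 of 47 members negative, a median of -0.54 and a camera adjusted p of 4.16e-14 (adjusted p = 0.572 with an estimated correlation). None passed limma over all probe sets (0, against 28 at an unadjusted p under 0.05), and 13 fell with the replicate block. Adjusted over the list alone, 15 passed lower, and with the block 37 passed lower and 1 higher (Cdc25a). The members with the smallest p were Dbf4, which activates the kinase Cdc7 (-0.70 ± 0.14 SE, adjusted p = 0.0741), and the licensing inhibitor Gmnn (-0.91 ± 0.19, 0.0813, and 0.0292 with the block). Dbf4 ranged from -0.80 to -0.41 over the 14 alternatives run. Cdc25a (0.29) and Orc1 (0.12), singled out after the values were seen, were the positive members and did not pass over all probe sets, and Orc1 turned negative (-0.10) as the mean of its probe sets.

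Among 20 G1 cyclins, their kinases and RB family members, Ccnd3 fell (-0.62 ± 0.09 SE; 1 of its other 2 probe sets had the opposite sign), 3 members passed lower when adjusted over the list alone (Ccnd3, Cks1b and Cks2), and the list shifted down (median -0.19, camera adjusted p = 7.18e-04; adjusted p = 0.572 with an estimated correlation). With the replicate block 4 fell, the fourth being Myc (-1.01 ± 0.30), and 6 passed lower when adjusted over the list alone. The 20 CDK inhibitors and antiproliferative genes did not pass the list test (median 0.07, camera adjusted p = 0.603). Their mean was higher in all 3 pairs by 0.04 to 0.05. None passed limma (0, against 6 at an unadjusted p under 0.05), 1 higher (Cdkn1a) and 3 lower (Cdkn2d, Cdkn3 and Gadd45b) passed when adjusted over the list alone, and 4 higher (Cdkn1a, Plk2, Gadd45g and Wee1) and 1 lower (Cdkn2d) with the block. With the block, the same 4 passed higher and the same 3 lower when adjusted over the list alone. Cdkn1a, the p21 inhibitor and a p53 target, read 0.51 ± 0.09 higher (adjusted p = 0.0624, and 0.0366 with the block), and Cdkn2d read -0.66 ± 0.14 (0.0905, and 0.0292 with the block).

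The p53 targets shifted up (23 members, 18 positive, median 0.31, camera adjusted p = 1.22e-05; adjusted p = 0.572 with an estimated correlation). Trp53inp1 (1.47 ± 0.13 SE) and the repair nuclease Ercc5 (0.75 ± 0.10) rose, and with the replicate block 5 rose (these, Eda2r, Ddit4l and Sesn2) and 1 fell. In all, 9 passed higher and 1 lower when adjusted over the list alone, and 14 and 1 with the block. The lower member was Sesn1 in each (-1.17 ± 0.20), a stress-induced inhibitor of mTORC1 signalling. The other probe set of Ercc5 had the opposite sign. The list mean was higher in all 3 pairs, by 0.22, 0.29 and 0.41 (exact permutation p = 0.1).

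**Figure D2:**
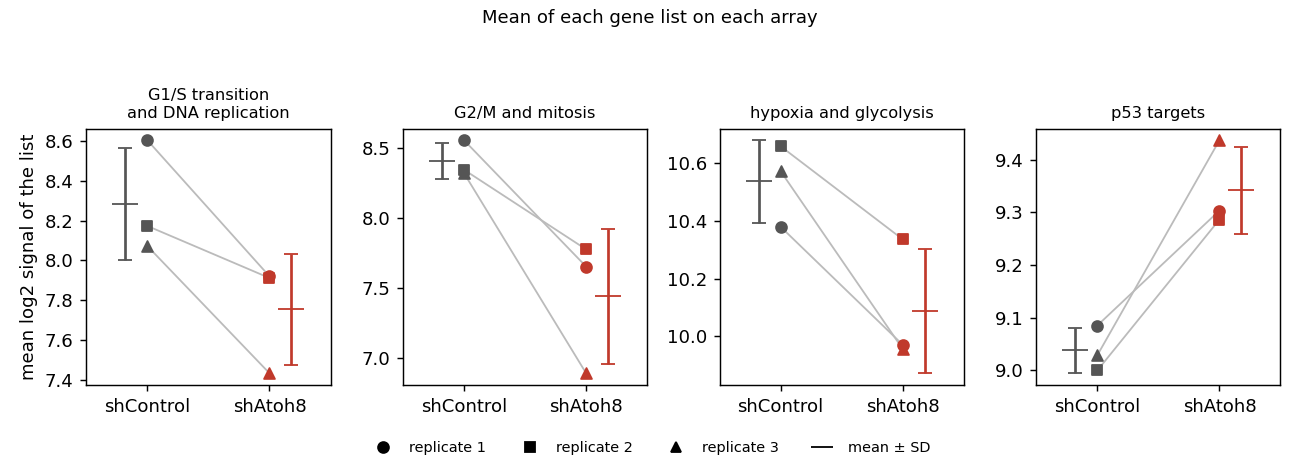
Mean log2 signal of 4 gene lists on each array, with lines joining arrays of the same replicate number and bars for the mean ± SD (n = 3); the vertical axes differ. The G2/M means lie at 8.32 to 8.55 in shControl and at 6.89 to 7.77 in shAtoh8, and the p53 targets lie higher in every pair.

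Hypoxia and glycolysis genes shifted down (31 members, 29 negative, median -0.51, camera adjusted p = 1.05e-09; adjusted p = 0.572 with an estimated correlation). None passed limma (0, against 16 at an unadjusted p under 0.05), and 13 fell with the block. Adjusted over the list alone, 11 passed lower, and 20 with the block. Aldoc, a glycolytic aldolase, read -0.57 ± 0.10 SE (adjusted p = 0.0664, and 0.0352 with the block) and Vegfa read -0.77 ± 0.16 (0.0864 and 0.0293). The NF-kB and inflammatory list (median -0.16, camera adjusted p = 2.68e-03), where Birc3 fell (-0.82 ± 0.12; its other probe set had the opposite sign), and the unfolded protein and integrated stress response list (median -0.12, 5.45e-03), where Dnajc3 (-0.68 ± 0.10) and the ER stress sensor Ern1 (-0.91 ± 0.14; 2 of its other 4 probe sets had the opposite sign) fell, also shifted down. So did the immediate early genes (median -0.18, 7.18e-04), with Maff at -0.88 ± 0.16 (adjusted p = 0.0609, and 0.0261 with the block) and Fos at -0.87 ± 0.17 (0.0711 and 0.0189), and cholesterol biosynthesis (median -0.18, 1.46e-03), where Hmgcs1 fell (-0.82 ± 0.12). With an estimated correlation the adjusted p was 0.572 for the first 3 of these lists and 0.579 for cholesterol biosynthesis. The cholesterol call was lost without shControl replicate 3 (0.0534) and without shAtoh8 replicate 2 (0.0544). Adjusted over the list alone, 4 NF-kB members (Birc3, Cxcl1, Relb and Nfkbia) passed lower, as did 1 cholesterol gene (Hmgcs1) and 5 immediate early genes (Maff, Fos, Ier3, Egr1 and Spry4), while Ier5 passed higher. In the stress response list 8 passed lower, among them Atf4 (-0.79 ± 0.21), Asns, Psat1, Chac1, Trib3 and Slc7a11, and 2 passed higher (Syvn1 and Eif2ak3). Over all probe sets Atf4, Asns and Trib3 passed in none of the 14 alternatives run at a threshold of 0.05, with a lowest adjusted p of 0.0875, 0.0653 and 0.0642. With the replicate block 5 NF-kB members (Birc3, Nfkbia, Ccl2, Il33 and Tnfaip2), 4 immediate early genes (Maff, Fos, Ier3 and Fosl1) and 1 cholesterol gene (Hmgcs1) fell, and 4 stress response members fell (Dnajc3, Ern1, Chac1 and Slc7a11) and 2 rose (Eif2ak3 and Sesn2). Adjusted over the list alone with the block, 13 NF-kB members passed lower and 1 higher (Il18), 13 stress response members lower and 3 higher (Syvn1, Eif2ak3 and Sesn2), 10 immediate early genes lower and 2 higher (Ier5 and Nr4a1), and 5 cholesterol genes lower (Hmgcs1, Mvd, Srebf2, Lss and Sc5d).

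Oxidative phosphorylation genes shifted up by a small amount (38 members, median 0.07, camera adjusted p = 0.0406; adjusted p = 0.728 with an estimated correlation), and the call was lost with the replicate block (0.0519), median centring (0.0621), brighter probe sets alone (0.0992), array weights (0.0862), fry (0.358) and fry with the block (0.267). It was also lost without shControl replicate 2 (0.0838), shControl replicate 3 (0.402), shAtoh8 replicate 1 (0.132) and shAtoh8 replicate 2 (0.0544). None of its members passed limma (0, against 4 at an unadjusted p under 0.05), over all probe sets or adjusted over the list alone. Sdha read 0.35 ± 0.09 SE (adjusted p = 0.137) and Ndufa5 0.36 ± 0.12 (0.222). Over the 14 alternatives run, Sdha ranged from 0.13 to 0.40 and Ndufa5 from 0.27 to 0.45.

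Lists of endocrine genes did not pass the list test. The list of endocrine factors includes Neurog3 itself, which the virus expressed. Whether its probe set reads the viral or the cells' own copy was not analysed. A lower Neurog3 there therefore cannot be assigned to either copy. No array lacked Neurog3 and levels of different probe sets cannot be compared, so whether the programme was on in these cells was not tested. The 22 endocrine transcription factors had a median of 0.05 (camera adjusted p = 0.671; median level 5.58) and the 36 islet hormone and secretory granule genes a median of 0.01 (0.671; median level 5.85). None passed limma in either list (0 and 0, against 2 and 3 at an unadjusted p under 0.05); adjusted over the list alone, 1 factor passed lower (Glis3), and 2 granule genes passed higher (Cck and Pcsk1) and 1 lower (Iapp). With the replicate block 1 factor rose and 1 fell (St18 and Neurog3 itself), and 2 granule genes rose (Cck and Pcsk1) and 2 fell (Iapp and Slc2a2). Adjusted over the list alone with the block, 2 factors passed higher (St18 and Rfx3) and 2 lower (Neurog3 and Glis3), and the same 4 granule genes passed. Iapp, the islet amyloid peptide, read -1.78 ± 0.39 SE (adjusted p = 0.0965) and the peptide hormone Cck read 1.85 ± 0.42 (0.105). Both passed with the replicate block (0.0189 and 0.0160), as did St18 (0.77 ± 0.29, adjusted p = 0.292 without and 0.0359 with it), while Glis3 did not over all probe sets (-0.66 ± 0.13, 0.0739 and 0.0631). With 1 array left out at a time St18 ranged from 0.51 to 1.08.

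In the Notch list (34 members, median 0.01, mean -0.05, camera adjusted p = 0.518, direction down) the receptor Notch1 rose (0.68 ± 0.10 SE) and the ligand Jag2 fell (-0.58 ± 0.09); 1 higher (Notch1) and 3 lower (Jag2, Nrarp and Notch4) passed when adjusted over the list alone, as they did with the replicate block. With the block Nrarp fell too (-0.60 ± 0.10, adjusted p = 0.0537 without and 0.0298 with it), giving 1 higher and 2 lower. Among 44 TGF-beta and BMP genes (median -0.03, 0.172) the receptor Tgfbr1 rose (1.29 ± 0.19) and its partner Tgfbr2 fell (-0.58 ± 0.08); 2 higher (Tgfbr1 and Bambi) and 3 lower (Tgfbr2, Bmpr2 and Tgfb3) passed when adjusted over the list alone, and the same 2 higher and 8 lower with the replicate block. Over all probe sets 2 rose (Tgfbr1 and Bambi) and 2 fell (Tgfbr2 and Bmpr2) with the block. Mitf rose (1.12 ± 0.15; 0.61 as the mean of its probe sets) among 42 bHLH and Id factors (median -0.00295, 0.603), and 1 higher (Mitf) and 1 lower (Bhlhe40) passed when adjusted over the list alone, with the block and without. Bhlhe40 (-0.71 ± 0.14, adjusted p = 0.0694) fell over all probe sets with the block (0.0375), giving 1 higher and 1 lower. The 34 ductal and epithelial genes did not pass the list test (median -0.04, 0.518). Their mean was lower in all 3 pairs, by -0.08, -0.08 and -0.04. None passed limma (0, against 6 at an unadjusted p under 0.05) or when adjusted over the list alone. With the block 1 fell (Epcam), and adjusted over the list alone 1 passed higher (Car2) and 2 lower (Epcam and Aqp1). Car2 read 0.60 ± 0.12 (adjusted p = 0.0853) and Epcam -0.73 ± 0.19 (0.145, and 0.0463 with the block; its other probe set had the opposite sign).

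The 44 mesenchymal and extracellular matrix genes had a median of -0.10 (camera adjusted p = 0.291), which passed without shControl replicate 1 (0.0257) and without shAtoh8 replicate 3 (0.0140). None passed limma (0, against 8 at an unadjusted p under 0.05) or when adjusted over the list alone, and 5 fell with the replicate block: Lamc1, Zeb2, Mmp3, Itga5 and Timp1 (for Timp1 -0.48 ± 0.11 SE, adjusted p = 0.0949 without and 0.0458 with the block); Itgav read 0.40 ± 0.10 (0.126). With the block, 2 passed higher (Itgav and Sparc) and 9 lower when adjusted over the list alone. Itgav ranged from 0.14 to 0.48 over the 14 alternatives run. The 42 interferon response genes had a median of 0.03 (camera adjusted p = 0.603), with 0 passing limma (10 at an unadjusted p under 0.05), 6 higher and 1 lower when adjusted over the list alone, and 3 higher (Trim25, Irgm1 and Usp18) and 1 lower (Psmb8) with the block. With the block, 6 passed higher and 1 lower when adjusted over the list alone. Psmb8 read -0.57 ± 0.10 (adjusted p = 0.0609, and 0.0294 with the block) and Trim25 0.51 ± 0.10 (0.0675 and 0.0416). Over the 14 alternatives run, Psmb8 ranged from -0.65 to -0.30 and Trim25 from 0.45 to 0.57. The 25 apoptosis genes had a median of 0.08 (camera adjusted p = 0.0943), with 0 passing limma, also when adjusted over the list alone (8 at an unadjusted p under 0.05); Casp8 read -0.35 ± 0.08 (0.106) and Endog -0.39 ± 0.10 (0.128). The 15 genes of the small RNA machinery did not pass the list test (median -0.08, mean 0.02, camera adjusted p = 0.750, direction up), and Tnrc6a rose (0.62 ± 0.08), the 1 member that passed when adjusted over the list alone.

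Ribosomal protein genes (30 of 47 listed, median -0.03, camera adjusted p = 0.160) did not pass the list test. Replication-dependent histones (6 of 27 listed, median 0.12, 0.505) did not pass either. As most listed histones matched no measured gene, this says little of the histones as a group. Neither list held a member that passed limma (0 and 0, against 0 and 1 at an unadjusted p under 0.05). Adjusted over the list alone, H1f2 passed, and with the block H1f2 and H2aw passed higher and H2bc21 lower. Rpl22 read -0.20 ± 0.10 SE and Rps27 -0.15 ± 0.10, and H1f2 read 0.50 ± 0.12 and H2aw 0.39 ± 0.20. With 1 array left out at a time Rpl22 ranged from -0.26 to -0.11 and Rps27 from -0.21 to -0.09. H1f2 then ranged from 0.38 to 0.57 and H2aw from 0.21 to 0.57. Markers of other cell types did not pass the list test: acinar cells (18 members, median 0.06, camera adjusted p = 0.0943, but 0.00586 without shControl replicate 2), neurons (20, 0.01, 0.895) and leukocytes and endothelium (19, 0.07, 0.603). The median levels of these lists were 5.17, 4.97 and 4.70, below the array medians of 5.49 to 5.56. With signals this low, the lists can say little about other cell types. The acinar mean was higher in all 3 pairs, by 0.19, 0.03 and 0.23. The groups did not overlap (exact permutation p = 0.1, the smallest possible). Rnase1 rose in the acinar list (1.32 ± 0.20) and Lyz2 in the leukocyte list (0.75 ± 0.12, adjusted p = 0.0499), each the 1 member that passed when adjusted over the list alone. With the replicate block Cd79a passed higher and Cd14 lower as well when adjusted over the leukocyte list alone. None of the 20 neuronal markers passed limma (0, against 1 at an unadjusted p under 0.05) or when adjusted over the list alone, and 1 rose with the replicate block, also over the list alone (Map2, 0.71 ± 0.43 without it). Nefl read -0.41 ± 0.14 and Ncam1 -0.28 ± 0.15. With 1 array left out at a time Map2 ranged from 0.31 to 1.09, Nefl from -0.53 to -0.28 and Ncam1 from -0.36 to -0.10. Another Ncam1 probe set was brightest without shControl replicate 2 or 3. Of the 16 lists that did not pass, 11 had a mean of one sign in all 3 pairs, 6 higher (CDK inhibitors, endocrine factors, islet hormones, apoptosis, histones and acinar markers) and 5 lower (ductal, Notch, TGF-beta and BMP, mesenchymal and ribosomal protein genes). The groups did not overlap for 3 of these, the apoptosis, ribosomal protein and acinar lists (exact permutation p = 0.1 each). An exact sign test over 3 pairs cannot go below 0.25.

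**Figure D3:**
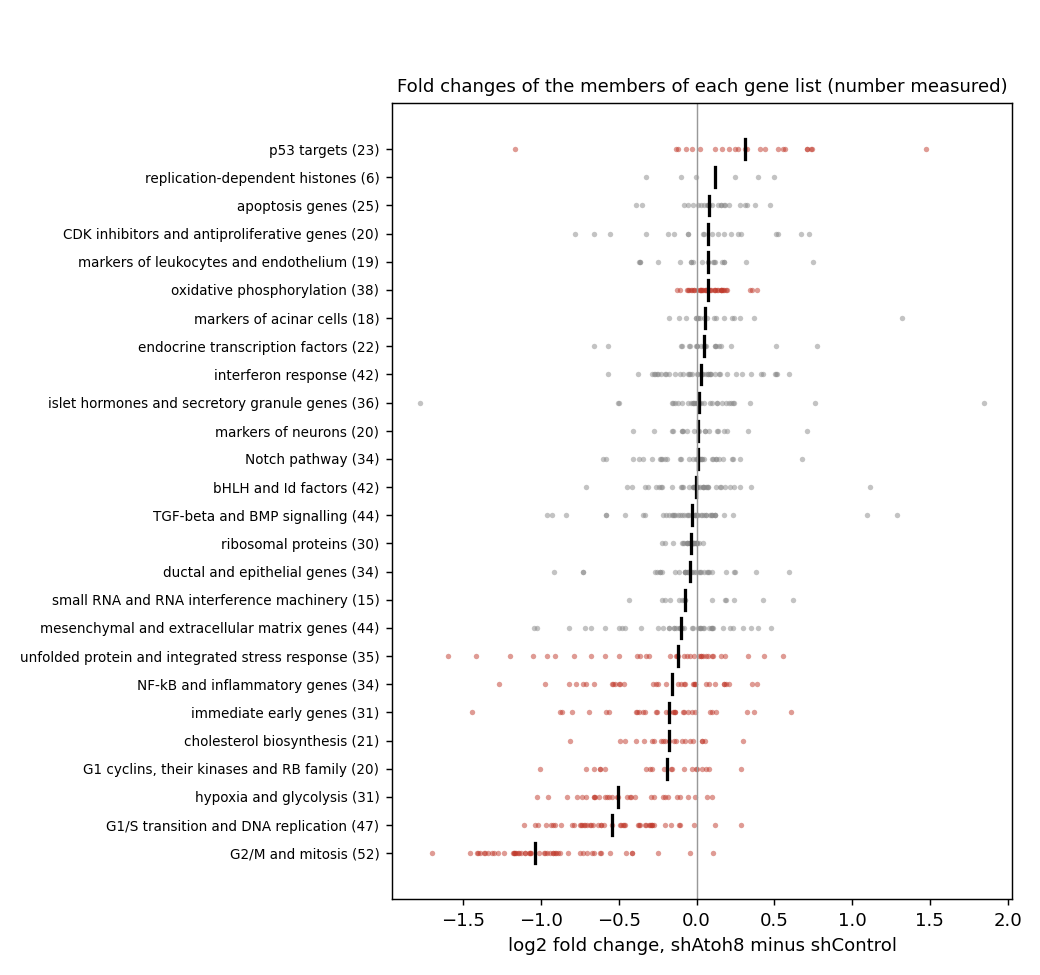
Log2 fold change (shAtoh8 minus shControl) of every measured member of the 26 gene lists, 1 point per gene, with a black bar at the list median; red marks lists with a camera adjusted p under 0.05 at the preset correlation. The G2/M list has its median at -1.04 and the p53 targets at 0.31, and 0 of the lists passed with an estimated correlation.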

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

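The number of changed genes ranged from 0 to 115 and of changed probe sets from 0 to 191 when 1 array was left out, with fewer arrays tested. Main counts were 210 genes and 361 probe sets. The replicate block gave 849 and 1541, the brighter probe sets 324 and 543, array weights 339 and 579, a threshold of 0.01 gave 0 and 1 (3191 and 6215 at an unadjusted p under 0.05), a threshold of 0.10 gave 691 and 1231, and the mean of a gene's probe sets gave 459 genes. The other alternatives stayed within 1.5 times, between 178 and 264 genes. Fits with the block, chosen after seeing the data, left out both arrays of 1 replicate number. Without replicate 1 or replicate 3 they gave 0 genes (2993 and 2568 at an unadjusted p under 0.05). Without replicate 2 the count was 962 (3928). These fits have fewer residual degrees of freedom, so they cannot show which replicates the count of 849 rests on. What made the counts differ was not tested.

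Of the lists 10 passed. With an estimated correlation 0 passed, with fry for one direction 0 and with fry and the replicate block 0; for G1/S, G2/M and G1 cyclins the adjusted p was 0.572, 0.186 and 0.118 in these tests. The fry test for changes in either direction, which compares a list with no other genes, passed for 16 lists and with the block for 22. Without 1 array 8 to 11 lists passed, and with median centring, brighter probe sets, array weights or the replicate block 9 passed, oxidative phosphorylation being lost (0.0621, 0.0992, 0.0862 and 0.0519). Under the trend alternative the list test used the variance trend without the robust step, which camera does not offer. Among lists that did not pass, the direction turned for markers of neurons (0.956 among brighter probe sets, 0.884 with the replicate block, 0.898 with fry, 0.415 with fry and the block, and 0.864 to 0.985 over the arrays left out), leukocytes and endothelium (0.804 among brighter probe sets), and with 1 array left out for small RNA (0.523 to 0.985), endocrine factors (0.201 to 0.977) and islet hormones (0.419 to 0.977). Orc1 turned to -0.10 as the mean of its probe sets. Atoh8 kept its sign and did not pass in all 14 alternatives run (-0.82 to -0.21, adjusted p 0.157 to 0.858), and Neurog3 on its brighter probe set (-0.57) passed with the replicate block. The block took the call of no gene called without it and changed no list call besides oxidative phosphorylation. Neurog3 ranged from -0.99 to -0.16 over the arrays left out.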

Other observations

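The tests of the G2/M list and of the Atoh8 probe set were chosen after the values were seen. The lysosome list was also written after the called genes had been seen, but its prediction was set before the list was tested as a whole. The fit that gave the calls had also given the values of its members. Its members Tfeb and Tfe3 are in the planned bHLH list too.

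The split by hairpin gave 210 genes, and the highest of the other splits of the 6 arrays gave 0 (limma; up to 1281 at an unadjusted p under 0.05, against 3191). It was 1 of 10 splits, too few for a share under 0.05. Among the 4 splits that part all 3 pairs, the fit with the replicate block gave 849 genes for the real one and at most 0 for the others (304 at an unadjusted p under 0.05), and 1 of 4 is again too few. The splits outside these 4 part 1 pair each. Every split but the real one mixes both hairpins in each group. A difference between hairpins would then add to the spread within groups and lower the number of genes called.

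The mean of the G2/M and mitosis genes was lower in shAtoh8, a shift that passed camera at the preset correlation but neither with an estimated correlation (adjusted p = 0.572) nor with fry (0.186). Each replicate number gave 1 array to each group, so a difference shared by both arrays of a number cancels in the group difference. The test of spread between numbers therefore cannot weigh it as a cause. The list mean was lower within every number, with a mean difference of -0.97 (SD 0.43, 3 pairs). As the groups had been seen not to overlap, that sign was fixed in advance. A single array as the whole cause was examined by leaving out each of the 6 arrays in turn. The smallest difference was then -0.69, against an SD of 0.13 between shControl arrays. That a difference remained follows from the same lack of overlap, so it is no separate test. It shows only that the difference does not rest wholly on 1 array. The shAtoh8 arrays spread more (SD 0.48, with replicate 3 at 6.89 against 7.65 and 7.77), so against their SD the remaining difference is less clear. A p53 response is a candidate explanation, since the mean of the p53 targets, which share 0 genes with the cell cycle lists, was higher by 0.30 (SD 0.10) over the pairs; this is the planned p53 list again, not a separate test. Its call was also lost with an estimated correlation (0.572) and with fry (0.0869), and p53 could itself respond to the virus or to an unintended target. A stronger antiviral response to one of the virus preparations cannot be told apart, because each hairpin came in its own virus; interferon genes differed by 0.035 (SD 0.076), higher in 2 of 3 pairs, and loss of Atoh8 itself stays open and untested.

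The Atoh8 probe set was lower in each pair (log2 fold change -0.49) but did not pass the test. How well the probe set responds to its transcript was not tested. Spread between replicate numbers may widen the error of the fold change, not its size. The standard error was 1.99 times as large without the replicate block as with it. The adjusted p with the block was still 0.157. The hairpin sequence was not analysed here, so whether the called genes respond to Atoh8 or to other targets of the hairpin stays open.

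Asah1 and Mfsd1 are lysosomal and were among the largest rises. A hypothesis is that lysosome and autophagy genes rose more widely. The list of 63 other such genes, 56 of them measured, was written with the called genes left out, so it could hold no called gene. Its mean was higher by 0.14 (SD 0.05) over the pairs, by 0.08, 0.16 and 0.19. The median fold change was 0.14 and 46 of 56 were positive. The camera p was 3.29e-05 at the preset correlation and 0.0818 with an estimated correlation, so a wider rise may be small and is not established when the genes' correlation is taken into account.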
